A study of Homo sapiens with 2 samples.

How the data were processed

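Single-cell RNA libraries of 2 samples, 1 FHF and 1 SHF, were prepared on a droplet platform (10X Genomics Chromium), per the labels' protocols. Groups were taken from the labels. Per the submitters' processing notes, the authors used Cell Ranger and STAR with the GRCh38 genome build. Tool versions, the gene annotation release, the strand setting and any filter are not given in the sources used here.

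The deposited files analysed here were a list of barcode names and a list of gene identifiers, symbols and feature types. Both were named as parts of a raw matrix. They are text and hold no measured unit. A count matrix was not analysed here. No depth, confidence interval, floor, fold change or test could be computed, and the planned comparison of summed UMIs and of cell clusters between FHF and SHF was not made. With 1 library per group it would have had no test in any case.

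From the lists, Python 3.11.15 counted features, symbols and barcodes. Features were matched by Ensembl identifier, without version, to the primary assembly gene annotation of GENCODE 29, which is on GRCh38. Of 33538 features, 33456 (99.8%) were found and 82 were not, and 385 of those found carry another symbol there. All coordinates, strands, gene types and exons come from GENCODE 29, whose gene models may differ from those used to make the files. Coordinates are 1-based. Symbols are those of the feature list.

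Marker lists were matched to the feature list by exact symbol. The rule for genes named singly was TBX5, NKX2-5, ISL1, TNNT2 and any list gene missing from the features or standing on more than 1. The lists, this rule and the alternatives were fixed before the data were examined. The overlap of list genes with neighbouring features was added after the lists had been read. An overlap needed at least 1 shared base, and exonic bases are the union of the exons of all transcripts of a gene, untranslated regions included. For RGS5 the protein-coding feature was used. The rule for overlap of whole gene spans was tested on a few made-up intervals with known answers. The count of shared exonic bases was not tested in this way.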

Results

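The series compared cardiomyocytes made from a human embryonic stem cell line and labelled first heart field (FHF) or second heart field (SHF). These fields are the progenitor pools from which different parts of the heart are built. The line, HES3, carries a tdTomato reporter at TBX5 and an eGFP reporter at NKX2-5. Cells were sorted on day 20 and profiled by droplet single-cell RNA sequencing. How the reporters or the sort defined the FHF and SHF groups is not described here. There was 1 FHF sample and 1 SHF sample, without replicates. Only a list of gene features and a raw list of barcode names were analysed here. Neither list holds a read or UMI count, so no expression level, depth, cell number, cluster or cell share is reported, and the comparison of FHF with SHF cells was not made. The values that follow say which heart field and cell type genes had a feature on which reads could be counted, and carry no information on whether a gene was expressed.

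All 108 genes of 17 marker lists fixed before the data were examined had a feature. The list genes are protein-coding, and the feature list held 99.6% of the protein-coding genes of the annotation. Full or nearly full coverage was therefore almost certain, and it says nothing about the 2 samples. All 6 first heart field genes and all 14 second heart field genes were present. So were 16 pan-cardiomyocyte genes, mostly of the sarcomere, and 6 ventricular-type, 8 atrial-type and 6 sinoatrial node-type genes. The lists also held 6 outflow tract genes and 11 genes of calcium and ion handling. Genes of cells that a sort might carry over were present as well, with 5 epicardial, 7 fibroblast, 5 smooth muscle, 6 endothelial, 6 pluripotent and 5 endoderm genes. The remaining lists were the 2 reporter loci, 6 proliferation genes and 6 stress genes, again with no member missing. Because 12 genes stood in 2 or more lists, the 121 list entries came to 108 different genes.

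TBX5, a T-box transcription factor of the first heart field and the locus of the tdTomato reporter, was listed as ENSG00000089225. It lies on the minus strand of chromosome 12 from 114353931 to 114408442 in GRCh38. NKX2-5, a homeobox transcription factor of cardiac progenitors and cardiomyocytes and the locus of the eGFP reporter, was listed as ENSG00000183072, on the minus strand of chromosome 5 from 173232109 to 173235357. ISL1, a LIM homeobox transcription factor of the second heart field, was listed as ENSG00000016082, on the plus strand of chromosome 5 from 51383391 to 51394738. TNNT2, which encodes cardiac troponin T, was listed as ENSG00000118194, on the minus strand of chromosome 1 from 201359008 to 201377762. Each of these 4 protein-coding genes had 1 feature. No symbol in the list named GFP, tdTomato or mCherry, and all identifiers were human Ensembl gene identifiers, so the reporter transcripts had no feature of their own.

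RGS5, a regulator of G-protein signalling placed in the second heart field and smooth muscle lists, was the only list gene whose symbol stood on 2 features, ENSG00000143248 and ENSG00000232995. The annotation classes the first as protein-coding and the second as antisense. Both lie on the same strand and share 534 exonic bases, which is 7.83% of the 6821 exonic bases of the protein-coding gene. A value given under the symbol RGS5 alone would therefore not say which feature it belongs to.

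Some list genes share exonic positions with a neighbouring feature in the annotation. How reads at these positions were assigned was not examined, and the strand setting of the counting is not given in the sources used here. Of the 108 genes, 31 shared exonic bases with a feature on the opposite strand, 8 with a feature on the same strand, and 72 with neither. The same shares over all features were not computed, so these counts cannot be read as particular to the list genes. TBX5 shared 252 of its 4363 exonic bases, or 5.78%, with the opposite-strand TBX5-AS1. TNNT2 shared 81 of 7259 exonic bases, or 1.12%, with LAD1 on the same strand. NKX2-5 and ISL1 overlapped no other feature. In the second heart field list 7 of 14 genes shared exonic bases with an opposite-strand feature, against 2 of 6 in the first heart field list. These counts rest on the cutoff of at least 1 shared base, and no other cutoff was tried. The shared parts ranged from 0.85% for JAG1 to 24.1% for HAND2 in the second heart field list. In the first heart field list they were 5.78% for TBX5 and 25.5% for NPPA. The genes of both lists are too few, and were picked rather than sampled, so the counts were not tested against each other.

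Further overlaps were picked out after they had been seen, and they are not a ranking by size. DDIT3 of the stress list, for instance, shared 27.2% of its exonic bases with the opposite-strand MARS. DDIT3 also shared 4.44% with the opposite-strand MBD6 and 8.03% with AC022506.1 on the same strand. HAND2, a basic helix-loop-helix factor of the second heart field, shared 24.1% of its exonic bases with the opposite-strand HAND2-AS1. NPPA, which encodes atrial natriuretic peptide, shared 25.5% with CLCN6, and the epicardial factor TCF21 shared 30.4% with TARID, both on the opposite strand. TNNI3, which encodes cardiac troponin I, shared 24.4% with AC010327.1 on the same strand. TTN, which encodes titin, shared 9.57% with the opposite-strand TTN-AS1 and smaller parts with other features on both strands.

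The feature list held 33538 genes under 33514 different symbols, of which 24 symbols stood on more than 1 feature. In the annotation used here, 19880 of the features were protein-coding, 7413 were long intergenic non-coding RNAs and 5465 were antisense genes. The protein-coding features made up 99.6% of the 19951 protein-coding genes of that annotation. The list held 13 mitochondrial genes by symbol. It held none of the 1879 microRNA, 1909 small nuclear RNA or 943 small nucleolar RNA genes annotated, and 251 of 15224 pseudogenes, so these small RNAs and nearly all pseudogenes had no feature to be counted on.

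The barcode list held 1474560 names, 737280 with the ending 1 and 737280 with the ending 2. The same 737280 sequences of 16 bases stood under both endings. The list was named as part of a raw matrix, so its length was not taken as a number of cells. No label tied an ending to the FHF or the SHF sample, so no barcode was assigned to either.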

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

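Counting features by distinct symbol instead of by identifier gave 33514 in place of 33538. Counting barcodes by sequence without the ending gave 737280 in place of 1474560 names, because each sequence stands under both endings. All 108 list genes were found with exact symbols, and 107 had exactly 1 feature, the exception being RGS5. Ignoring case and punctuation also gave 108, but it could only add matches and so could not have changed a full count. The 4 other settings fixed in advance, on scaling, cell filters and clustering, were not run, since they need a count matrix. Overlaps were computed on GENCODE 29 gene models only, and the effect of another release was not tested. The cutoff of at least 1 shared base was not varied either.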
